A study of Mus musculus with 29 samples.

How the data were processed

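RNA from 28 mouse lung tumours and 1 normal lung was hybridized to Affymetrix expression arrays, 1 array per sample. The labels give total RNA, extraction with RNeasy columns, a 2-cycle target preparation and a biotin label. Each deposited value is an intensity, a signal for 1 probe set on a linear scale. The submitters' processing notes name MAS5, whose version is not given in the sources used here. No value was below 0, and the 2% trimmed mean was 500.003 in every array, so the arrays were used as deposited. The series text names the MOE430A 2.0 array, but the deposited table holds 45101 probe sets, more than that array carries. Arrays have no read depth, and their number limits the precision.

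Probe sets were assigned to genes with the platform annotation and a RefSeq gene table of the GRCm38.p6 mouse genome. Of all probe sets, 64 were hybridization controls, 34958 named 1 gene, 932 named several and 9160 named none. Matching by gene identifier placed 34754 on the gene table. A probe set was kept if it exceeded the 40th percentile of its own array in at least 6 arrays, and 31932 passed. The probe set with the highest mean represented each gene, which left 14602 genes, 14517 of them with a chromosome. An offset of 20, the 20th percentile of all deposited values rounded, was added before the log2. Fold changes on that log2(value + 20) scale understate changes of weakly expressed genes.

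The samples were grouped by their source labels into normal lung, TI-K primary tumours, TI-KM primary tumours and TI-KM recurrences. Replicate numbers only order the samples within a group. All 29 arrays entered 1 limma model (version 3.58.1 in R 4.3.3, with the data.table package, version 1.17.8, for reading) with the 4 groups as its only term and a variance trend. A gene was called changed at a Benjamini-Hochberg adjusted p below 0.05 over all genes tested; about 730.1 genes would reach an unadjusted p below 0.05 by chance. The normal lung is 1 array, so its own spread is unknown and was assumed to equal that of the tumour groups. Lists of genes, 37 in all with 837 members of which 720 were measured, covered pathways and the cell types a lung tumour sample can hold. They were tested with camera from limma at a preset correlation of 0.01, again with an estimated correlation, and with fry, each adjusted over the 37 lists. Members of a list were also adjusted over the list alone.

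The genes named were fixed by a rule. It takes Mad2l1 in every comparison, and the 7 largest higher and 7 largest lower called genes of each comparison between tumour groups. It also takes the 2 members with the smallest p from up to 6 called lists. For normal lung it takes the 6 largest changes each way, and 2 members each of the alveolar type II, alveolar type I, club, ciliated and endothelial lists. List members picked this way are examples, not further evidence. The rule also names the gene of the KrasV12 transgene, which the annotation did not hold, so it was not analysed here.

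A pair of scores was computed per tumour array. The spread score is the root mean square, over the genes kept, of the array's residual from its group mean, corrected for group size. The chromosome score is the SD over the 19 autosomes of the median residual of each autosome's genes, divided by its mean over 200 shufflings of genes among chromosomes; it measures expression shared along a chromosome, not copy number. Differences of group means were tested with 2-sided exact permutation tests, adjusted over the 3 pairs of groups.

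The groups, tests, lists, named-gene rule and most alternatives were chosen before the data were examined. The alternatives were other scalings, offsets, filters, variance models and choices of probe set, the fit of 2 groups alone, averaging of a pair of tumours that share title number 76, inferred sex and the 3'/5' ratio of the control transcripts as covariates, TI-K tumours by title number, and leaving out each array in turn. Sex was inferred from Xist and Y-linked genes. After the data were seen, 3 sets of arrays were defined from the 18S ribosomal control signal (threshold 12000) and the TI-K title numbers, because they split the samples within groups. The sets then entered the model as a block for the 28 tumour arrays, and the comparisons were repeated within sets. The normal lung, at 12569, lies above the threshold but was left out of the block; its comparisons were repeated with the high-18S arrays only and with the remaining arrays only.

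The model was tested on simulated data in which 100 genes changed 2-fold and 100 changed 4-fold. It recovered 72 and 96 of them for TI-KM against TI-K primaries (9 false calls), and 68 and 95 for recurrences against TI-KM primaries (6 false calls). For recurrences against TI-K primaries the counts were 54 and 92 (5 false calls), and against the normal lung 6 and 46 (4 false calls). With the sets as a block, the 3 tumour comparisons recovered 57 and 93, 77 and 98, and 48 and 84; among the 13 arrays of the remaining set, TI-KM against TI-K recovered 29 and 78. A list shifted by 0.50 was found, alone among the 37. The simulated genes varied independently, without co-expression and without shifts between array sets. These counts therefore do not show how the gene and list tests behave where either is present. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9 and numpy 2.4.6.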

Results

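The study profiled RNA from mouse lung tumours driven by transgenes that respond to doxycycline. TI-K mice carried CCSP-rtTA, which places the reverse tetracycline transactivator in airway epithelium, and a KrasV12 transgene under the tetracycline-responsive TRE promoter. TI-KM mice carried in addition a TRE transgene for Mad2, a protein of the spindle checkpoint that holds cells in mitosis until chromosomes are attached. The series title concerns relapse of such tumours after the oncogene is withdrawn. The arrays covered 8 TI-K primary tumours, 14 TI-KM primary tumours, 6 TI-KM recurrences and 1 normal lung from a mouse with CCSP-rtTA alone, all of a mixed 129/Bl6 background. TI-KM replicates 1 and 2 share the title number 76 and may come from 1 animal. The limma and permutation p-values of the tumour comparisons measure the spread between these samples. Camera p-values at the preset correlation do not take the correlation between list members from these samples. P-values against the normal lung borrow its spread from the tumour groups, so they do not measure the spread between normal lungs. Inferred sex was female and male in 4 and 4 TI-K primaries, 4 and 10 TI-KM primaries, and 2 and 4 recurrences; the normal lung was male. TI-K primary 3, counted as female, had both an Xist signal (log2 9.17) and a Y-linked signal in the range of males (7.61), so its sex is not settled.

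The arrays fell into sets that the labels do not name. In 10 arrays, 6 TI-KM primaries (replicates 1 to 6) and 4 recurrences (replicates 1 to 4), the 18S ribosomal control signal was 12665 to 24001 and the median signal 122 to 170, and these lay apart on the first principal component. A further 5 TI-K primaries (replicates 1 to 5) carry title numbers far above those of the other tumours. The remaining 13 arrays held 3 TI-K primaries, 8 TI-KM primaries and 2 recurrences, with an 18S signal of 5939 to 10857. No TI-K primary is in the high-18S set. Within TI-KM primaries, 6174 genes differed between the high-18S and the remaining arrays (limma, adjusted p below 0.05; 7381 at unadjusted p below 0.05), and within TI-K primaries 2323 differed between high-number and remaining arrays (4727 unadjusted). Between the sets of recurrences limma called 0 genes, with 3188 at unadjusted p below 0.05. The log2 3'/5' ratio of the control transcripts, a sign of RNA integrity, was 2.16 ± 0.41 (SD, n = 8) in TI-K primaries, 2.16 ± 0.67 (n = 14) in TI-KM primaries, 1.32 ± 0.45 (n = 6) in recurrences and 2.59 in the normal lung. Because the sets fall unevenly over the groups, each tumour comparison is given with the sets as a block and within sets.

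**Figure D1:**
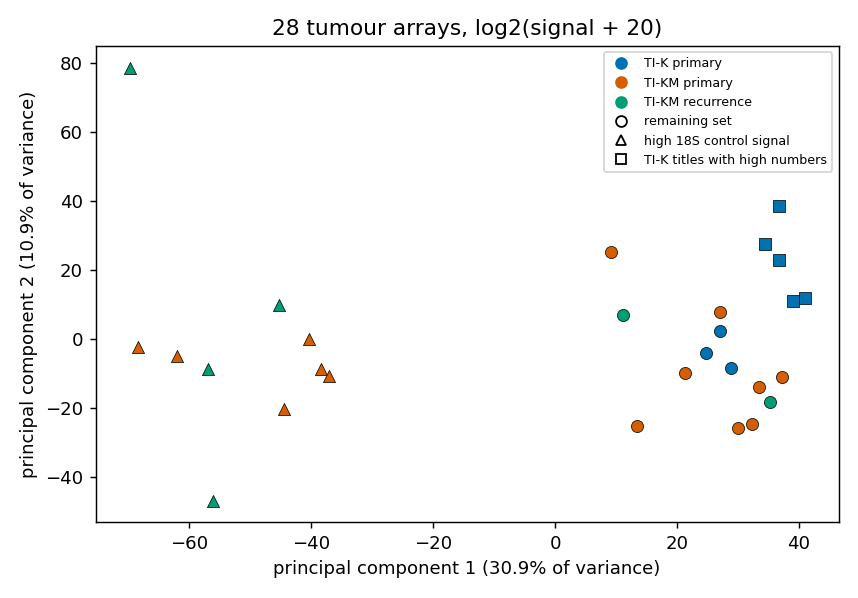
Principal components 1 and 2 of the 28 tumour arrays on log2(signal + 20); each point is an array, coloured by group, with its array set shown by the marker. The 10 high-18S arrays lie between -69.8 and -37.0 on component 1 (30.9% of the variance) and the other 18 tumour arrays between 9.23 and 40.9.

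Tumours had more alveolar type II and epithelial transcripts and fewer fat and mitochondrial ones than the 1 normal lung array. Of 20 measured genes of alveolar type II cells, which make surfactant, 14 rose and 0 fell in TI-K primaries (16 and 0 adjusted over the list alone), with a median log2 change of 2.25. Napsa, a protease that processes surfactant protein B, rose 16.8-fold (log2 4.07 ± 0.37 SE, n = 8 and 1, limma adjusted p = 4.61e-09), and Sftpd, a surfactant protein, rose 5.37-fold. Another probe set of Napsa gave log2 2.68. Among 25 genes of epithelial junctions and keratins, 21 rose (23 adjusted over the list alone; median 2.42). The 25 oxidative phosphorylation genes fell in 17 cases (22 adjusted over the list alone; median -1.40), and 4 of 5 adipocyte genes fell (4 adjusted over the list alone; median -3.78). Each of these 4 lists passed with an estimated correlation too (adjusted p = 0.0264).

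The genes named for their increase in TI-K primaries were Prm1, the sperm protamine, at log2 7.94 ± 1.92 SE (adjusted p = 0.00462), the EGF-receptor ligand Ereg at 6.77 ± 1.23 (adjusted p = 2.44e-04) and Serpinb5 (maspin) at 6.19. The others were Lcn2, the siderophore-binding lipocalin, at 6.12 ± 0.39 (adjusted p = 3.06e-12), the claudin Cldn2 at 5.99 and the costimulatory ligand Tnfsf9 at 5.90. Other probe sets gave 0.73 for Cldn2, 3.88 and 7.77 for Prm1, and 3.64 to 5.57 for Serpinb5. The normal lung signals of Prm1 (2.86), Serpinb5 (2.82), Cldn2 (8.92) and Tnfsf9 (9.85) lay below the offset of 20, so these sizes depend on the offset and their order is no ranking. The largest decreases were Cidea, a lipid-droplet protein of brown fat, at -9.30 ± 0.79 (adjusted p = 1.34e-09; median TI-K signal 5.25, below the offset, which sets the size), Thrsp, a regulator of lipogenesis, at -7.39, and the carbonic anhydrase Car3 at -6.85. Cox7a1 fell by 6.68, Fabp3 by 6.53 and the lipase Pnpla3 by 6.39. Other probe sets gave -0.63 for Fabp3, -5.81 for Thrsp and -8.44 for Car3. The normal lung had signals of 17182 for Cidea, 23610 for Thrsp and 10925 for Car3, and the sources used here do not say whether that sample held fat. The lower adipocyte and oxidative phosphorylation values are therefore differences from this array, not a shown loss in tumours. The higher alveolar type II and epithelial junction values are likewise differences from this array, not a shown gain. Aqp5, a water channel, rose by 2.98 and Krt7 by 2.59, both members of the alveolar type I list, while 3 of the 16 measured members of that list rose and 1 fell (3 and 2 adjusted over the list alone; list adjusted p = 0.487). Endothelial Gpihbp1 and Kdr (VEGF receptor 2) fell by 2.07 and 2.86.

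Other lists passed camera in TI-K primaries but not with an estimated correlation. Proliferation genes were higher: 10 of 30 spindle checkpoint and kinetochore genes rose (14 adjusted over the list alone; median 1.36; adjusted p = 0.303 with an estimated correlation), 9 of 24 mitotic cyclins and kinesins (10 over the list alone; 1.32; 0.433 likewise), and 6 of 28 DNA replication genes with 1 lower (10 and 1; 0.82; 0.468). Of the 69 measured genes of the CIN70 signature, an expression signature named for chromosomal instability, 13 rose and 2 fell (19 and 3 adjusted over the list alone; median 0.84; adjusted p = 0.468 with an estimated correlation). RAS-MAPK output genes rose in 7 of 23 cases (14 over the list alone; 1.38; 0.303), macrophage genes in 7 of 24 with 2 lower (9 and 2; 0.84; 0.468) and antigen presentation genes in 4 of 13 (5; 0.87; 0.468). With the remaining arrays only, the medians of the last pair were 1.32 and 1.78. Lower lists were endothelial with 10 of 23 genes falling (14 over the list alone; median -1.61; adjusted p = 0.285 with an estimated correlation), smooth muscle and pericyte with 4 of 14 (7; -1.63; 0.284) and neuroendocrine with 5 of 11 (6; -1.86; 0.284). Cholesterol and fatty acid synthesis had 6 of 24 lower and 1 higher (7 and 1; -0.48; 0.468), erythroid genes 3 of 6 lower and 1 higher (3 and 1; -1.37; 0.284) and fibroblast and matrix genes 1 of 26 each way (0 over the list alone; -0.89; 0.643). None of 24 ciliated genes passed limma, alone or over the list, at a median of -1.84 (list adjusted p = 9.38e-04, and adjusted p = 0.605 with an estimated correlation), with Spag16 at -2.50 (adjusted p = 0.112) and Dynlrb2 at -2.88 (adjusted p = 0.113). The club cell list missed the threshold (adjusted p = 0.0663; median -1.35; 2 of 18 lower, 0 over the list alone), though its members Gsta3 and Fmo2 fell by 2.23 and 2.16. Another probe set of Gsta3 gave -0.56.

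In all, limma called 1976 genes between TI-K primaries and the normal lung (984 higher, 992 lower), 2177 for TI-KM primaries (1132 and 1045) and 1833 for recurrences (944 and 889). These comparisons share 1 normal array, assumed to vary like the other groups, so they are not independent, and any peculiarity of that sample enters each of them. Its 18S signal was 12569, above every remaining and high-number array and nearer the high-18S set, which holds no TI-K primary. With the high-18S arrays only, limma called 2210 and 1727 genes for TI-KM primaries and recurrences, and in TI-KM primaries the medians were 1.95 for alveolar type II, 2.52 for epithelial junction, -1.44 for oxidative phosphorylation and -3.24 for adipocyte genes. With the remaining arrays only, the calls were 3483, 3839 and 2932, and in TI-K primaries those medians were 2.16, 2.41, -1.06 and -4.39. Camera called 18, 21 and 19 of the 37 lists, and with an estimated correlation 4, 4 and 0, the smallest adjusted p for recurrences being 0.0628. In TI-KM primaries the same 4 lists passed with an estimated correlation (adjusted p = 0.0279): epithelial junction genes rose in 23 of 25 cases, alveolar type II genes in 14 of 20, oxidative phosphorylation genes fell in 15 of 25 and adipocyte genes in 4 of 5. Lists called for TI-KM primaries but not for TI-K primaries were the unfolded protein response (median 0.48, adjusted p = 0.0299), mesenchymal transition (-0.38, 0.0491; but 0.16 with the high-18S arrays only and -0.54 with the remaining arrays only) and cardiac and skeletal muscle (-1.34, 0.0403), with adjusted p = 0.426, 0.589 and 0.578 with an estimated correlation. For recurrences, the unfolded protein response (median 0.70, adjusted p = 7.77e-04) and the gastric and gut lineage (1.20, 0.0411) were called beyond those of TI-K primaries, and ciliated genes were not (-0.48, 0.452; 0.089 with the high-18S arrays only and -1.32 with the remaining arrays only); with an estimated correlation the first pair gave adjusted p = 0.246 and 0.579. A list called in 1 group and not in another is not thereby shown to differ between them. Scaling the arrays to a common median moved the median change of all genes in TI-K primaries from 0.00 to 0.13 and the calls to 1202, 1395 and 1079.

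**Figure D2:**
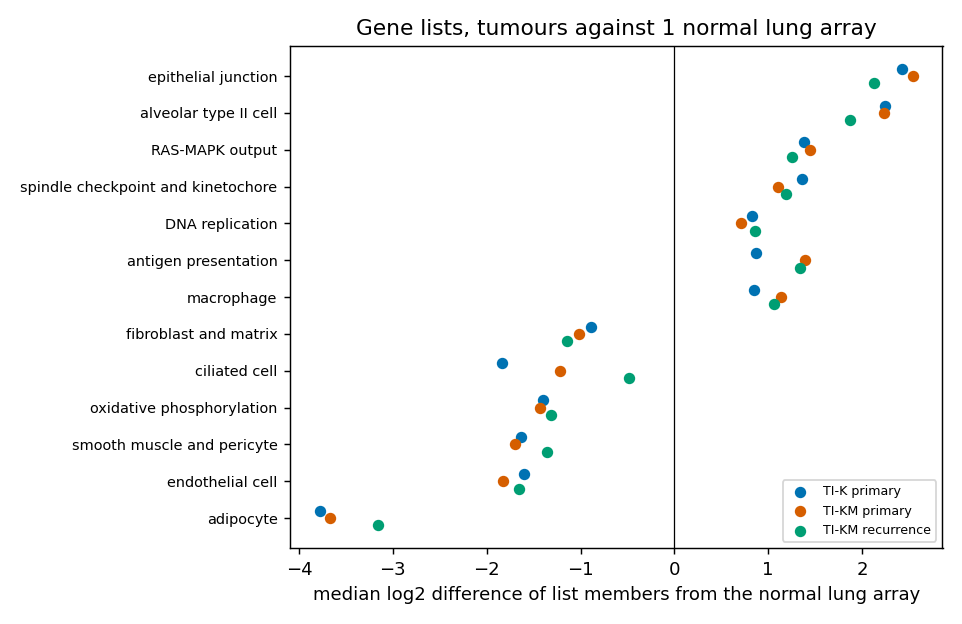
Median log2 difference of the members of 13 gene lists from the 1 normal lung array (horizontal axis) in TI-K primaries, TI-KM primaries and recurrences (points, coloured by group); a positive value means higher in the tumours. The alveolar type II median is 2.25 in TI-K primaries, and the adipocyte median -3.78.

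Mad2l1, the mouse gene for Mad2, had 1 probe set. Its signal was 938 ± 319 (SD, n = 8) in TI-K primaries, 751 ± 207 (n = 14) in TI-KM primaries, 868 ± 563 (n = 6) in recurrences and 340 in the normal lung. TI-KM minus TI-K primaries was -0.29 ± 0.22 SE on the log2 scale (limma adjusted p = 0.399; -0.38 with the sets as a block), recurrences minus TI-KM primaries 0.04 (adjusted p = 0.961; block 0.10) and recurrences minus TI-K primaries -0.25 (adjusted p = 0.523; block -0.28). Against the normal lung the values were 1.35, 1.06 and 1.095 (adjusted p = 0.0891, 0.185 and 0.192); with the remaining arrays only, TI-K primaries were at 1.55 (adjusted p = 0.0289). The sources used here do not say whether this probe set reads the transgene.

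TI-KM against TI-K primaries asks what the Mad2 transgene adds to KrasV12 tumours. Bambi, a decoy receptor that dampens TGF-beta signalling, rose 6.33-fold in TI-KM primaries (log2 2.66 ± 0.61 SE, n = 14 and 8, limma adjusted p = 0.0124): its signal was 566 to 1108 in TI-K and 621 to 21184 in TI-KM, with 10 of 14 TI-KM tumours above every TI-K tumour. Cda, the cytidine deaminase of pyrimidine salvage, rose 4.65-fold (log2 2.22 ± 0.35, adjusted p = 0.00564), and 12 of 14 lay above every TI-K tumour. The other large increases were MHC class II genes H2-Eb1 (2.64, adjusted p = 0.00627) and H2-DMb2 (2.25, adjusted p = 0.0234), the lysosomal galactosylceramidase Galc (2.61), Cd200r4 (2.50) and C2cd4b (2.13). The largest decreases were C030013C21Rik (-2.06), AI506816 (-1.84), Erdr1 (-1.83), the sialic acid lyase Npl (-1.75), the metalloreductase Steap4 (-1.75), the zinc finger gene Zfp458 (-1.69) and the lung mesenchymal long noncoding RNA Fendrr (-1.66). Of 26 measured fibroblast and matrix genes, 4 fell and 0 rose (4 and 0 adjusted over the list alone; median -0.22, adjusted p = 0.0148, and adjusted p = 0.928 with an estimated correlation), among them the collagen gene Col5a2 (-0.97, adjusted p = 0.0136) and the PDGF receptor gene Pdgfra (-1.102, adjusted p = 0.0242). Other probe sets of Pdgfra gave -0.05 and 0.25, and the other one of Erdr1 gave 0.06.

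limma called 1166 genes between these groups (803 higher, 363 lower; 266 at least 2-fold). With the sets as a block it called 0, with 709 at unadjusted p below 0.05 and a smallest adjusted p of 0.0658. The high-number set holds only TI-K primaries, so the blocked comparison rests on the 3 remaining TI-K primaries. Among the remaining arrays alone, 8 TI-KM against the same 3 TI-K, limma called 0, with 1028 unadjusted. These fits are therefore not independent checks, and both use fewer TI-K arrays than the main fit. Bambi and Cda lost their call, at 3.26 (adjusted p = 0.507) and 2.44 (adjusted p = 0.324) with the block and 3.50 and 2.54 among the remaining arrays. Their changes did not shrink, but their SEs were larger with the block (0.90 and 0.53) than without it (0.61 and 0.35). The remaining TI-K signals of Cda (5.84 to 19.04) lay below the offset of 20, which sets the size of its change. H2-Eb1 was 0.16 with the block and -0.021 among the remaining arrays. Its signal was 404 to 902 in the 5 high-number TI-K tumours, 10074 to 14810 in the other 3 and 407 in the normal lung. The block values were -0.26 for H2-DMb2, -1.36 for Cd200r4, 1.05 for Galc and 0.55 for C2cd4b. Among the decreases they were -0.54 for C030013C21Rik, -1.104 for AI506816, -1.08 for Erdr1, -0.89 for Npl, -0.28 for Steap4, 0.053 for Zfp458, -0.26 for Fendrr, -0.42 for Col5a2 and -0.25 for Pdgfra. The fibroblast and matrix median was 0.04 with the block (adjusted p = 0.473) and 0.08 among the remaining arrays. The count also rested on single arrays: it was 396, 477, 419, 398 and 432 without TI-K replicates 1, 2, 3, 4 and 5 in turn, and 755, 755 and 756 without TI-KM replicates 1, 2 and 4.

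**Figure D3:**
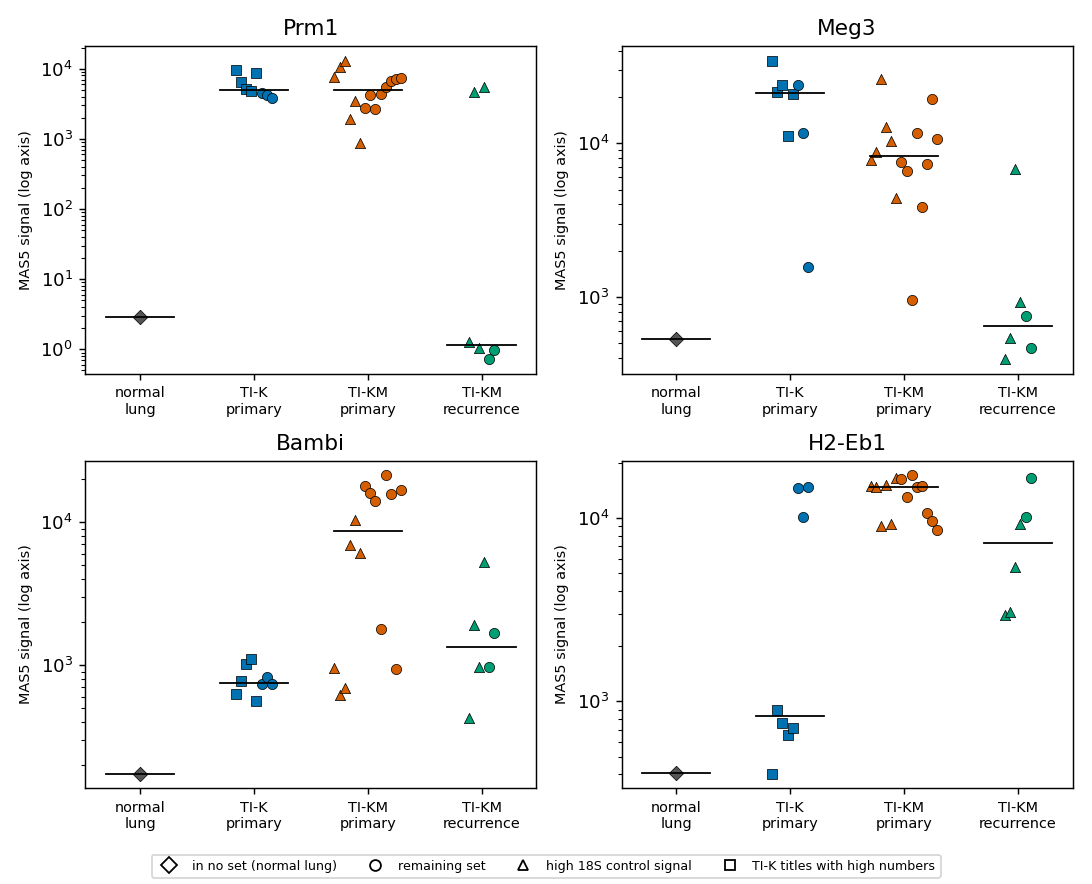
Deposited signals (log axis) of Prm1, Meg3, Bambi and H2-Eb1 in each array (points), by group, with the array set shown by the marker and the group median by a line. On the probe set drawn, Prm1 is near background in the normal lung and 4 of 6 recurrences, and Bambi exceeds the highest TI-K value in 10 of 14 TI-KM primaries.

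Recurrences against TI-KM primaries compare relapsed with primary tumours of 1 genotype. On the probe set that represents it, Prm1, high in all 22 primaries (signal 872 to 12918), was 0.729 to 1.28 in recurrences 1, 3, 5 and 6 but 4705 and 5521 in recurrences 2 and 4, a mean log2 change of -5.12 ± 0.88 SE (n = 6 and 14, limma adjusted p = 0.00894). On the weakest of its 3 probe sets, recurrences 1, 3, 5 and 6 read 139, 170, 60.8 and 39.9, against 9.51 in the normal lung and at least 254 in every primary, so some signal remained there. All 3 are _x_at probe sets, so Prm1 had no value in the alternative without _x_at and _s_at probe sets. Meg3, a maternally expressed long noncoding RNA, fell 8.68-fold (log2 -3.12 ± 0.57, adjusted p = 0.0138), with 5 of 6 recurrences below every TI-KM primary. Other decreases were the p53-responsive cell-cycle gene Rprm (-1.77), the plasma protein gene Itih4 (-1.75, adjusted p = 0.00473), the mannosidase Manea (-1.81), the nuclear noncoding RNA Firre (-1.73) and the DNA demethylating enzyme Tet2 (-1.72). Slc2a3, the glucose transporter GLUT3, rose 8.29-fold (log2 3.05 ± 0.61, adjusted p = 0.0264), and Cckar, the cholecystokinin A receptor, rose 6.90-fold (log2 2.79 ± 0.59, adjusted p = 0.0306), each above every TI-KM primary in 4 of 6 recurrences. The actin regulator Enah (1.89), the glutathione transferase Gstm2 (1.77), the monooxygenase Fmo2 (1.54, 5 of 6 recurrences above every TI-KM primary) and Rusc2 (1.44) rose too. These 6 genes were also higher in the normal lung than in the median TI-KM primary: 1972 against 227 for Slc2a3, 1013 against 198 for Cckar, 3489 against 448 for Enah, 1316 against 271 for Gstm2, 8172 against 1444 for Fmo2 and 355 against 21.8 for Rusc2. Other probe sets gave -0.017 and 1.12 for Enah, -0.31 for Tet2, -4.76 and -1.28 for Prm1, and -3.67 to -0.12 for Meg3 (10 of them).

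In the 6 lists that camera called here, no single member passed in limma over all genes. Ciliated cell genes were higher (23 of 24 positive, median 0.86, camera adjusted p = 8.57e-07, and adjusted p = 0.853 with an estimated correlation), and so were unfolded protein response genes (20 of 22 positive, 0.31, 3.92e-04, and 0.718 likewise). Club cell genes (0.64) and B and plasma cell genes (0.57) missed the threshold (camera adjusted p = 0.0516 for both), though limma called the club cell list member Fmo2. DNA replication genes were higher as well (22 of 28 positive, 0.25, 0.0175, and 0.853), as were mesothelial genes (8 of 10 positive, 0.63, 0.0272, and 0.853). Alveolar type II genes were lower (17 of 20 negative, -0.23, adjusted p = 1.01e-04, and 0.791 with an estimated correlation), as were epithelial junction genes (21 of 25 negative, -0.28, 3.92e-04, and 0.853). Adjusted over the list alone, 3 unfolded protein response genes and 1 mesothelial gene passed higher, 2 alveolar type II genes passed lower, and 0 passed in the other 3 lists. Recurrence 1 stood apart on component 2 (78.8) and was low in Napsa, Aqp5, Lcn2 and Esrp2. Without it the epithelial junction median turned to 0.022 (adjusted p = 0.815), and alveolar type II (-0.12, adjusted p = 0.101), DNA replication (0.069, adjusted p = 0.741) and mesothelial genes (0.48, adjusted p = 0.158) lost their call. Ciliated genes (0.51, adjusted p = 0.00379) and the unfolded protein response (0.17, adjusted p = 0.00767) kept it. Interferon response genes (-0.41, adjusted p = 0.00379; -0.093 with all arrays) and endothelial genes (0.18, adjusted p = 0.0341; 0.17 with all arrays) gained a camera call. No list passed with an estimated correlation. As examples, the chaperones Pdia4 and Pdia3 were at 0.80 and 0.81, the ciliary genes Cfap126 and Fam183b at 1.21 and 1.77, and mesothelial Lrrn4 and Upk3b at 1.28 and 1.69. The alarmin Il33 was at -0.83, the claudin Cldn18 at -0.61, the epithelial splicing factor Esrp2 at -0.68 (-0.29 without recurrence 1), and the replication genes Cdc45 and Pola1 at 0.64 and 0.61; another probe set of Cdc45 gave -1.01.

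limma called 38 genes (6 higher, 32 lower; 1809 at unadjusted p below 0.05). With the sets as a block it called 102 (18 higher, 84 lower), which included all 38, whose changes kept a median of 98.2% of their size. Block values were -5.35 for Prm1, -3.28 for Meg3, -1.78 for Rprm, -1.57 for Itih4, -1.71 for Manea, -1.89 for Firre, -1.67 for Tet2, 2.90 for Slc2a3, 2.68 for Cckar, 1.86 for Enah, 1.54 for Gstm2, 1.62 for Fmo2 and 1.48 for Rusc2. Within sets, Prm1 was -7.83 among the remaining arrays (2 recurrences) and -3.70 among the high-18S arrays, sizes set by the offset and by how many recurrences lack the signal. In the same order, Meg3 was -3.42 and -3.19, Slc2a3 3.97 and 2.19, and Cckar 3.36 and 2.23. In all, 12 genes were called among the former and 1 among the latter. List medians with the block, then within the remaining and the high-18S arrays, were 0.66, 0.13 and 0.997 for ciliated cells, 0.29, 0.06 and 0.44 for the unfolded protein response, and 0.28, 0.42 and 0.19 for DNA replication. They were 0.50, 0.27 and 0.47 for mesothelial cells, -0.19, -0.09 and -0.26 for alveolar type II cells, and -0.19, -0.17 and -0.29 for epithelial junctions. The 3'/5' ratio was lower in recurrences, and with it as a covariate limma called 0 genes, with 854 at unadjusted p below 0.05. The count was 12, 13, 17, 25 and 142 without recurrences 1, 2, 3, 5 and 6, and 15 without TI-KM primary 13.

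Recurrences against TI-K primaries differ in both genotype and relapse. Sox2, a transcription factor of airway and basal epithelium, rose 13.9-fold (log2 3.80 ± 0.86 SE, n = 6 and 8, limma adjusted p = 0.00466), with 5 of 6 recurrences above every TI-K tumour. Cckar rose by 3.43 ± 0.65 (adjusted p = 0.00127), the desmosomal cadherin Dsg2 by 3.10, the interferon gene Ifna2 by 2.72, the dynein light chain Dynlrb2 by 2.44, neutrophil surface Cd177 by 2.44 and Speer4f1 by 2.43. The largest decreases were Prm1 (-5.42), Meg3 (-3.99 ± 0.64, adjusted p = 3.23e-04) and Neat1, the scaffold RNA of nuclear paraspeckles (-3.78 ± 0.59, adjusted p = 2.73e-04). Gdpd3 (-3.18), C030013C21Rik (-3.13), the angiogenin gene Ang3 (-3.11) and A530020G20Rik (-3.10) followed. Other probe sets gave 0.64 for Neat1, -2.10 and -0.25 for A530020G20Rik, -5.15 and -1.15 for Prm1, and -5.30 to 0.051 for Meg3, where 9 of 10 were negative.

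Ciliated genes rose in 14 of 24 cases (17 adjusted over the list alone; median 1.49, camera adjusted p = 3.18e-05, and adjusted p = 0.978 with an estimated correlation), among them the axonemal dynein Dnah9 at 1.76 (adjusted p = 0.00650). Unfolded protein response genes rose in 5 of 22 cases (5 adjusted over the list alone; median 0.43, adjusted p = 0.0184, and 0.978 with an estimated correlation), with Pdia4 at 1.34 and the chaperone Hsp90b1 at 0.74; another probe set of Hsp90b1 gave -0.14. Of 20 alveolar type II genes, 1 fell (0 adjusted over the list alone; median -0.31, adjusted p = 0.00365, and 0.978 with an estimated correlation): the calcium-binding S100g fell by 1.103, and surfactant Sftpc was at -0.46 (adjusted p = 0.0602), with another probe set at -3.00.

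limma called 2745 genes here (1775 higher, 970 lower), and 14 with the sets as a block (3 higher, 11 lower; 10 shared with the 2745). Among the remaining arrays, 2 recurrences against 3 TI-K primaries, it called 19. The blocked comparison rests on the same 3 TI-K primaries, because the high-number set holds only TI-K primaries. None of the genes named for this comparison passed with the block: Sox2 was 3.27 (adjusted p = 0.263), Cckar 3.61 (0.111), Meg3 -3.53 (0.0938), Neat1 -3.12 (0.0635), Prm1 -5.67 (0.0973), A530020G20Rik -2.36 (0.0980) and Cd177 4.21 (0.120). The other block values were 2.51 for Dsg2, 1.63 for Ifna2, 1.43 for Dynlrb2, 0.33 for Speer4f1, -1.68 for Gdpd3, -1.47 for C030013C21Rik, -1.52 for Ang3, 0.99 for Dnah9, 1.20 for Pdia4, 0.45 for Hsp90b1, -1.60 for S100g and -0.26 for Sftpc. The block medians were 0.995 for ciliated genes (adjusted p = 9.46e-06), 0.44 for the unfolded protein response (1.75e-07) and -0.13 for alveolar type II cells (0.393), and with an estimated correlation the first pair did not pass (adjusted p = 0.991 and 0.192); among the remaining arrays the first pair were 0.47 and 0.37. Median scaling moved the median of all genes from 0.11 to 0.01. The 3'/5' ratio as a covariate left 1543 calls, and the count was 1607, 1690 and 1798 without recurrences 2, 3 and 4.

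The series concerns a mitotic checkpoint gene, so tumours were compared for how far they differ within their group. The spread score was 0.454 ± 0.066 (SD, n = 8) in TI-K primaries, 0.562 ± 0.089 (n = 14) in TI-KM primaries and 0.679 ± 0.142 (n = 6) in recurrences. The differences were 0.108 for TI-KM minus TI-K primaries (2-sided exact permutation p = 0.00640, adjusted p = 0.00960), 0.117 for recurrences minus TI-KM primaries (exact p = 0.0349, adjusted p = 0.0349) and 0.225 for recurrences minus TI-K primaries (exact p = 0.00133, adjusted p = 0.00400). On the most highly expressed genes alone, the first pair of differences lost their call, at 0.0820 and 0.109 (exact permutation, adjusted p = 0.0793 for both). Measured from the mean of each group within its array set, they were 0.0787, 0.126 and 0.205 (exact permutation, adjusted p = 0.0209, 0.0209 and 0.00300). Inside 1 set, remaining TI-KM and TI-K primaries had 0.441 ± 0.084 (n = 8) and 0.416 ± 0.051 (n = 3; exact p = 0.691, adjusted p = 0.903). High-18S recurrences and TI-KM primaries had 0.660 ± 0.148 (n = 4) and 0.495 ± 0.059 (n = 6; exact p = 0.0333, adjusted p = 0.133 over 4 tests). The smallest p those designs allow is 0.00606 and 0.00476. The recurrence against TI-KM difference lost its call without TI-KM primary 1 (adjusted p = 0.0597) or 6 (0.0552), or recurrence 1 (0.163), 3 (0.0638) or 6 (0.0746), in exact permutation tests.

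**Figure D4:**
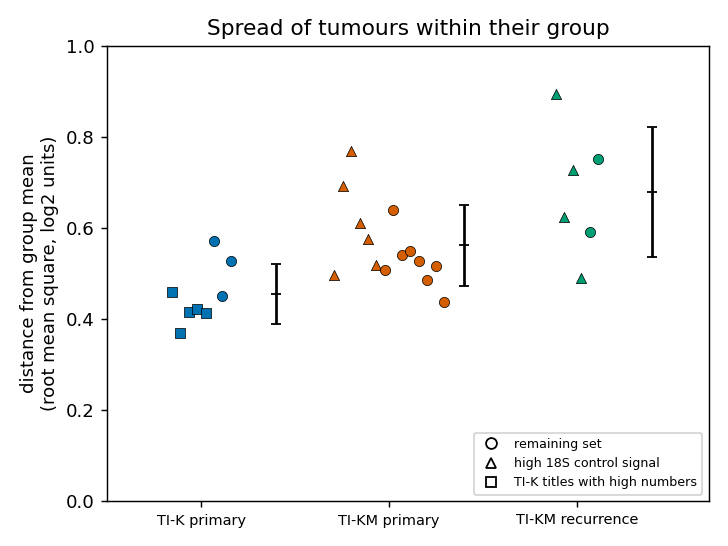
Spread score (root mean square distance from the group mean, log2 units) of each tumour array (points), by group, with the array set shown by the marker and the group mean and SD by the bar beside the points. The means are 0.454, 0.562 and 0.679 in TI-K primaries, TI-KM primaries and recurrences.

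The chromosome score, shared expression along chromosomes relative to shuffled genes, was 2.22 ± 1.57 (SD, n = 8) in TI-K primaries, 2.00 ± 0.62 (n = 14) in TI-KM primaries and 2.03 ± 1.28 (n = 6) in recurrences. No pair of groups differed by more than the spread between tumours (2-sided exact permutation p = 0.733, 0.947 and 0.814; adjusted p = 0.947 for each; adjusted p = 0.363, 0.718 and 0.718 within array sets). The TI-K mean rested on replicate 5 (5.97, next 2.29): without it TI-KM minus TI-K primaries went from -0.212 to 0.574 and recurrences minus TI-K primaries from -0.183 to 0.603, and neither passed. On simulated arrays with 3 chromosomes shifted by 0.3 log2 units, whose genes otherwise varied independently, the score averaged 2.47, against 1.04 without a shift. The simulated noise followed neither the spread nor the co-expression of the real arrays. These values therefore give no scale for the real scores and do not show what shift the group comparison could detect.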

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

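Tests chosen only after the result was seen were those of the array sets, of the Mad2 genotype and of Prm1 transcript from a transgene; the lists of nuclear RNAs were written after the called genes were seen and hold Clk1, called with and without the block, and Neat1 and Ccnl2, called with it. In 17 of 152 groups of 4 to 10 arrays, 1 array lay further from its neighbour than Dixon's 95% limit on the share of the group's range allows; chance gives about 1 in 20, or 7.6.

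TI-K replicate 8 accounted for 5 of these, each on the low side. Its share of the range was 0.635 for Meg3 (signal 1573, next 11200), 0.584 for Neat1 (588, next 4214), 0.622 for Firre, 0.650 for A530020G20Rik and 0.528 for Erdr1. Recurrence 1 accounted for another 5, also low: 0.731 for Serpinb5 (4.25, next 927), 0.784 for Lcn2 (6512, next 17274), 0.761 for Aqp5 (916, next 7608), 0.711 for Esrp2 and 0.644 for Napsa (4438, next 10388). TI-K replicate 5 was low in Napsa (0.531) and Rprm (0.588) and high in its chromosome score (0.737; 5.97, next 2.29), with chromosome 12 deviating most at a median residual of 0.16. TI-K replicate 4 was high in Cidea (0.622), recurrence 2 in Cox7a1 (0.648), recurrence 3 in Meg3 (0.704; 6835, next 930) and recurrence 4 in Cda (0.628).

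The 1166 genes called between TI-KM and TI-K primaries are the first pattern weighed. Of 100 splits of the 22 arrays, 1, the real one, called as many, and the highest other split called 2. These splits mixed the array sets, so they cannot exclude chance given the sets. Splits inside the sets were not run for this pair. The array sets remain a candidate explanation, since 6174 genes differed between sets within TI-KM primaries and limma called 0 genes with the sets as a block (709 at unadjusted p below 0.05). That block leaves 3 TI-K primaries to carry the comparison, so calls can also be lost through fewer arrays. The Mad2 genotype cannot be told apart from the sets: a median of 31.4% of the change was left with the block (quartiles 15.1 and 53.5), with 1035 of 1166 genes keeping their sign, and no TI-K tumour is in the high-18S set. Bambi, at 3.26 with the block but no longer called, may be a gene to measure in further tumours.

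Prm1 was lower in 4 of 6 recurrences, near background on the probe set that represents it but at 39.9 to 170 on the weakest. The array sets do not account for this, since 2 of the 4 high-18S recurrences were below 100 on the first of these and the other 2 were not, and the weakest parts them alike (139 and 170 against 594 and 602). Of 18 other listed spermatid genes 9 were measured, with a median change of 0.24 (quartiles 0.06 and 0.49) where Prm1 fell by 5.12. That goes against a spermatid programme but does not exclude it. The signal levels of these genes were not examined, and a gene near background cannot fall. A transgene transcript that carries Prm1 sequence stays open: Prm1 was 2.86 in the normal lung, which has no TRE transgene, and at least 872 in every primary. The recurrences with less signal could then express less of the transgenes, a hypothesis that the transgene sequences, not given in the sources used here, would test.

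Some nuclear RNAs were lower in recurrences than in TI-KM primaries, among them Meg3, Firre and, with the block, Neat1. A change confined to the imprinted Meg3 locus is argued against by Firre outside it (-1.89 ± 0.33 SE with the block). Other probe sets of Firre gave -1.71 and -1.23 without the block. Neat1 (-2.52 ± 0.45 with the block) is weaker evidence, as limma did not call it without the block (adjusted p = 0.0593). Another probe set of Neat1 gave 0.64 against TI-K primaries. Both genes were picked because they were called. The listed nuclear noncoding RNAs outside the Meg3 locus had a median of -0.57 with the sets as a block. The 3'/5' ratio as a covariate beside the sets left 78.9% of the change of 6 called RNAs (70.4 to 86.3). These were Meg3, Firre, Rsrp1, Luc7l, Zfp207 and Tet2, picked because they were called. The share left argues against the measured ratio as the whole cause, but RNA integrity that the ratio misses was not tested. The limma calls fell from 102 to 2 (1183 at unadjusted p below 0.05). Meg3 went from -3.28 ± 0.57 SE (limma adjusted p = 0.00569) to -2.59 ± 0.62 (adjusted p = 0.176), a smaller change with a larger error. A lower share of nuclear RNA in the recurrence samples stays open, because its lists hold called genes: 12 detained-intron transcripts had a median of -0.61 and 10 nuclear noncoding RNAs -0.75 with the block, or -0.47 and -0.63 without the 2 and 1 called, and 2 and 1 members were above 0. Without the block 1 and 0 of them were called, and tissue handling was not tested.

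Splits of the other tumour comparisons mix the array sets too, so they showed the structure of the samples. For recurrences against TI-KM primaries, 3 of 100 splits called at least the real 38 genes; the highest other called 1230, with all 6 arrays of its smaller group from the high-18S set, and another called 356, with 5. Splits that kept the number of recurrences in each set argue against chance for the blocked count but do not exclude it. Of 100 such splits, 1, the real one with 102, called as many. The highest other called 41, and 85 of the others called 0. The block itself was chosen after the data were seen. For recurrences against TI-K primaries, 1 of 100 splits, the real one with 2745, called as many, but the highest other called 2711 with all 4 high-18S arrays in its smaller group, which leaves the sets open. The blocked count was 14, and only 10 splits inside the sets exist there, too few for a share under 0.05.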

How the results depend on the processing

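The array sets as a block, the comparisons within sets the residual within sets and the lists without recurrence 1 were chosen after seeing the data; the other alternatives were planned. Of the results that answer a comparison, 119 values under alternatives kept their side of the threshold, or a count within 1.5 times. A further 37 counts moved by more and 2 differences lost their call. A change of sign was counted as a reversal only where the main fit or the alternative called the value. Uncalled values that changed sign are therefore among those that held. Of named genes, 1215 values held, 185 lost their call, 5 gained one and 12 reversed. Leaving out 1 array changed 112 of the named-gene values to no call and 5 to a call, and reversed 0.

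Counts that moved by over 1.5 times, against 1166 for TI-KM against TI-K primaries, were 1870 with quantile normalization, 4173 with array weights, 765 with the title 76 pair averaged, 2571 with the high-number TI-K tumours only, and in limma 0 with the 3 low-number TI-K tumours only (842 at unadjusted p below 0.05), 0 with the block (709) and 0 among the remaining arrays (1028). Against 38 for recurrences and TI-KM primaries they were 72 with quantile normalization, 11 with the 2 groups alone, 15 with array weights, 0 with the 3'/5' ratio (854), 102 with the block, 12 among the remaining and 1 among the high-18S arrays. Against 2745 for recurrences and TI-K primaries they were 1543 with the ratio, 0 with the low-number TI-K tumours only (2445), 14 with the block and 19 among the remaining arrays. Median scaling gave 1202, 1395 and 1079 calls against the normal lung for TI-K primaries, TI-KM primaries and recurrences, and array weights 3308 and 3291 for the first pair; with the normal lung and the remaining arrays only, they were 3483, 3839 and 2932. The 2-group, title and within-set fits also used fewer arrays, and some of them called more genes; the cause of these moves was not tested.

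Lists called went from 1 to 0 with an estimated correlation, 0 with fry and 10 with the block for TI-KM against TI-K primaries; from 6 to 0, 0 with fry and 10 with quantile normalization for recurrences against TI-KM primaries, where 4 were called with recurrence 1 left out; and from 3 to 0, and 7 with the block, for recurrences against TI-K primaries. Against the normal lung an estimated correlation left 4, 4 and 0. That setting changed only how camera treats the correlation between list members, so those losses follow from it. The cause of the other moves was not tested. The spread differences on the most highly expressed genes alone were 0.0820 for TI-KM minus TI-K primaries and 0.109 for recurrences minus TI-KM primaries (exact permutation, adjusted p = 0.0793 for both); fewer genes were used there.

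Reversed genes, called in the main fit or the alternative, were all between TI-KM and TI-K primaries. They were Erdr1 without _x_at and _s_at probe sets (0.064), and with the low-number TI-K tumours only, H2-Eb1 (-0.014), Cd200r4 (-1.27), H2-DMb2 (-0.33) and Zfp458 (0.030). With the block they were Cd200r4 (-1.36), H2-DMb2 (-0.26) and Zfp458 (0.053), and among the remaining arrays H2-Eb1 (-0.021), Cd200r4 (-1.42), H2-DMb2 (-0.50) and Steap4 (0.060). For Erdr1 another probe set was used, and each of the other settings drops or adjusts for the high-number TI-K arrays. Uncalled values changed sign elsewhere too. In recurrences against TI-KM primaries, Cdc45 ran from -0.18 to 0.85 over the alternatives and Mad2l1 from -0.22 to 0.19.

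Leaving out 1 array gave 396 to 1609 genes for TI-KM against TI-K primaries, 12 to 142 for recurrences against TI-KM primaries and 1607 to 3933 for recurrences against TI-K primaries. Spread differences ranged from 0.0887 to 0.131, 0.0650 to 0.162 and 0.173 to 0.271 in the same order, and chromosome score differences from -0.450 to 0.574, -0.662 to 0.359 and -0.874 to 0.603. No paired analysis was possible because the labels pair no samples. Signals near background limit fold changes: Prm1 in the normal lung was 2.86, below the offset of 20.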

Other observations

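The tests with the array sets as a block were chosen after the data were seen, and the genes and lists below after their values were seen. With the block, other genes passed in recurrences against TI-KM primaries, of which Cox7c, Clk1, Rsrp1 and Luc7l passed without it too. Lower were Neat1 (-2.52, limma adjusted p = 0.00588), A330023F24Rik (-2.02, adjusted p = 0.00287), the synaptic organizer gene Cbln1 (-1.92) and the cytochrome oxidase subunit gene Cox7c (-1.85), while Hhip, an inhibitor of hedgehog signalling, rose by 1.49. Clk1 (-1.28, adjusted p = 0.00569), Rsrp1 (-1.59), Rbm25 (-1.46), Ccnl2 (-1.38) and Luc7l (-0.79) were lower as well. Against TI-K primaries, the aldehyde dehydrogenase Aldh3a1 rose by 2.92 (adjusted p = 0.0137; 0.22 without the block), Fmo2 by 2.55 and the protocadherin Pcdhb17 by 1.08. Lower there were A930007I19Rik (-2.52; without the block -0.72, adjusted p = 0.242), Firre (-2.49), Snord89 (-2.16), Zfp207 (-1.81), Anks3 (-1.72) and Ifnz (-1.64; without the block -0.72, adjusted p = 0.157).

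Between TI-KM and TI-K primaries the block gave 10 called lists against 1 without it, none of which passed with an estimated correlation (smallest adjusted p = 0.841). Macrophage genes had a median of -0.49 (adjusted p = 3.08e-04), interferon response genes -0.41 (6.66e-05; 0.15 without the block), neutrophil genes -0.33 (0.0494; 0.034 without), mitotic cyclins and kinesins -0.37 (2.64e-04) and spindle checkpoint and kinetochore genes -0.24 (0.0343). Higher were MYC targets at 0.14 (8.88e-05), unfolded protein response genes at 0.19 (0.00539), club cell genes at 0.31 (0.00265), epithelial junction genes at 0.21 (0.0104) and endothelial genes at 0.16 (0.0343; -0.12 without), so the block turned the direction of the interferon, neutrophil and endothelial lists. In recurrences against TI-K primaries with the block, MYC targets were at 0.33 (2.10e-07, and adjusted p = 0.192 with an estimated correlation) and interferon response genes at -0.57 (1.33e-04, and 0.991; 0.11 without the block).

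Sox2 had a signal of 716 to 4789 in recurrences 1 to 5 and 27.7 in recurrence 6. Slc2a3 was highest in recurrences 2 (9851) and 5 (11031), and Cckar in recurrence 5 (7035).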
